A study of Mus musculus with 4 samples.

How the data were processed

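Binding of the transcription factor STAT3 was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in cells dissociated from the spinal cord of C57BL/6 mice, 7 days after a laminectomy alone (sham) or a laminectomy with a contusion (SCI). The series holds 4 samples, 1 STAT3 ChIP library and 1 input library for each of the 2 conditions, and tissue of 3 mice was pooled for each library. The 2 STAT3 peak lists were analysed, and each was matched to its sample by the sample's title. The input libraries were not analysed here.

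Reads were aligned with Bowtie2 to the mouse genome build mm10, per the submitters' processing notes. The peak caller, its control and its threshold are not given in the sources used here. The deposited lists give each peak's position with a score, the authors' own value for the strength of that peak, which was 5 or more in every row. They also give a −log10 value that stands where the deposited layout places a q-value, and it lay between 3.27 and 4.05 in sham and between 3.22 and 4.36 in SCI. Read counts per library are not part of these lists, so the sequencing depth of the libraries is unknown. The score was used to describe, rank and filter peaks within a list. Whether scores of the 2 lists are on the same scale is not given in the sources used here, so values of both lists printed together are no measure of a difference in binding.

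Peaks on chromosomes 1 to 19, X and Y were used. A peak was called shared when it overlapped a peak of the other list by at least 1 bp. The overlap was set beside 100 shuffles of the peaks within their chromosomes, between the first and the last peak of each chromosome. Shares carry 95% exact binomial (Clopper-Pearson) intervals, which cover counting error only. Gene positions came from the RefSeq annotation of GRCm38.p6, whose primary chromosomes have the mm10 coordinates, with 49943 genes of which 21887 are protein-coding. A gene had a peak when a peak centre lay inside it or within 5 kb on either side. The table used here has no strand and no exons. The planned share of peaks at transcription start sites was therefore replaced by the share of peak centres within 1 kb of either end of a gene, the upstream window of genes became a window on both sides, and peaks are described as inside or outside a gene. The planned search for the STAT motif needs the genome sequence and was not run.

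For each of 13 gene lists the members with a peak were counted and placed among 10000 random lists of the same size, drawn from protein-coding genes in the same deciles of gene length. The percentile is the percent of random lists with fewer members with a peak, plus 0.5 times the percent with the same number. The lists were study genes, JAK-STAT3 pathway and known STAT3 targets, reactive astrocyte, resting astrocyte, microglia and macrophage, neuron, oligodendrocyte lineage, vascular and fibroblast, neutrophil and lymphocyte, glial scar matrix, cell cycle, EMT (epithelial to mesenchymal transition) and Zeb family, and housekeeping. These lists, the tests, the alternatives and the rule for the genes to be named were chosen before the data were examined. By that rule the text names the study genes, the genes at the 10 highest-scoring peaks of each condition that lie at a gene, the genes at the 10 shared peaks whose lower rank of the pair was best, and, for each list, up to 4 members with a peak in SCI alone and up to 2 with a peak in sham alone, taken by their best rank. The gene at 1 of the 10 highest sham peaks is not reported here. With 1 library per condition no test between conditions was run, and percentiles among random lists describe these libraries only.

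The overlap and list counts were tested on simulated data. Planted overlaps of 5, 20 and 50% among 36249 peaks came back as 4.93, 20.1 and 50.0% after the shuffled level was taken off. Among 21887 genes, 191 of 200 lists with planted peaks and 6 of 200 lists without passed the upper 2.5% bound. These lists had 30 genes each, the peaks were shuffled SCI peaks, and planted lists gained peaks at many members that had none. Weaker effects, other list sizes and sham peaks were not tried. A search for a repeated step in the scores recovered both of 2 simulated step sizes. The alternatives were a score at or above the list median, equal numbers of top-scoring peaks, 4 other rules for a shared peak, 3 other gene windows, 5 kb around gene ends, ends of protein-coding genes only, all sequences, merged peaks, a score cut at the median of both lists together, and random lists also matched on peak density within 1 Mb. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.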

Results

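STAT3 is a transcription factor activated by cytokines of the interleukin-6 family, and in astrocytes it takes part in the reaction to injury. The series concerns the response of astrocytes to spinal cord injury and the long noncoding RNA gene Zeb2os. Here STAT3 binding was profiled in cells dissociated from the injury epicentre 7 days after surgery. Sham mice received a laminectomy at thoracic level 9. SCI mice also received a moderate contusion of 60 kdyn at that level. The labels' protocols describe digestion and filtering of the tissue and no sort for 1 cell type. Each condition had 1 STAT3 ChIP library and 1 input library, each from pooled tissue of 3 mice, so there are no replicates and no difference between sham and SCI given here has a replicate check.

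The sham list of the STAT3 ChIP held more peaks than the SCI list on every autosome and on X. Whether these peaks are sites of STAT3 binding was not checked, since the motif search was not run. On chromosomes 1 to 19, X and Y it had 88765 peaks and the SCI list 36249, a ratio of 2.45. By chromosome the ratio lay between 2.14 on chromosome 17 and 2.82 on chromosome 13, and Y had 8 sham and 10 SCI peaks. The authors' score had a median of 8.07 in sham and 7.37 in SCI, and 1% of the peaks exceeded 39.3 and 27.7. The peaks were of nearly fixed width, 190 bp for 99.01% of the sham peaks and 164 bp for 99.4% of the SCI peaks. The narrowest had 50 bp in both lists, and most of the highest peaks named below were narrower than the usual width. No input signal and no list of artefact-prone regions was used here to filter peaks, so artefacts among the highest peaks are possible.

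At Zeb2 and Zeb2os, both conditions had a peak at the same place. Zeb2 encodes a zinc-finger repressor, and Zeb2os (gene ID 433424, chromosome 2, 45111138 to 45114087) lies within the span of Zeb2 (gene ID 24136, chromosome 2, 44983512 to 45117442). The sham peak at 45115187 to 45115376 had a score of 22.4 and lay in the top 6.62% of the sham list. The SCI peak at 45115205 to 45115368 had a score of 6.74, in the top 60.2% of the SCI list. Both lay inside Zeb2, and their centres were 1195 and 1200 bp outside Zeb2os. SCI had a further peak inside Zeb2, at 45035127 to 45035290, with a score of 14.4 in the top 10.2% and no sham peak over it.

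Stat3 itself had peaks in both conditions, while Gfap and Socs3 had none in either. Stat3 (gene ID 20848, chromosome 11, 100886806 to 100939594) held 3 sham and 3 SCI peaks, and 1 further SCI peak lay 2330 bp outside it; 2 of the positions inside were shared. Its highest SCI peak, at 100894297 to 100894460, had a score of 19.96 and ranked 1299 in the SCI list, the top 3.58%. The sham peak there had a score of 6.10, in the top 74.4%. The highest sham peak at Stat3, at 100929380 to 100929569, scored 16.1 in the top 14.5% and was not in the SCI list. Gfap, the intermediate filament of astrocytes (gene ID 14580, chromosome 11, 102887336 to 102897200), had its nearest sham peak 23.1 kb away and its nearest SCI peak 119 kb away. Socs3, the feedback inhibitor induced by STAT3 (gene ID 12702, chromosome 11, 117966079 to 117970336), had its nearest sham peak at 9.31 kb and its nearest SCI peak at 6.55 kb. Presence or absence of a peak at these genes has to be read beside gene length. In the length decile of Zeb2, 99.2% of protein-coding genes had a sham peak and 92.7% an SCI peak. The shares were 87.8 and 58.7% in the decile of Stat3, 57.2 and 29.7% in that of Gfap, and 46.3 and 23.5% in that of Socs3.

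**Figure D1:**
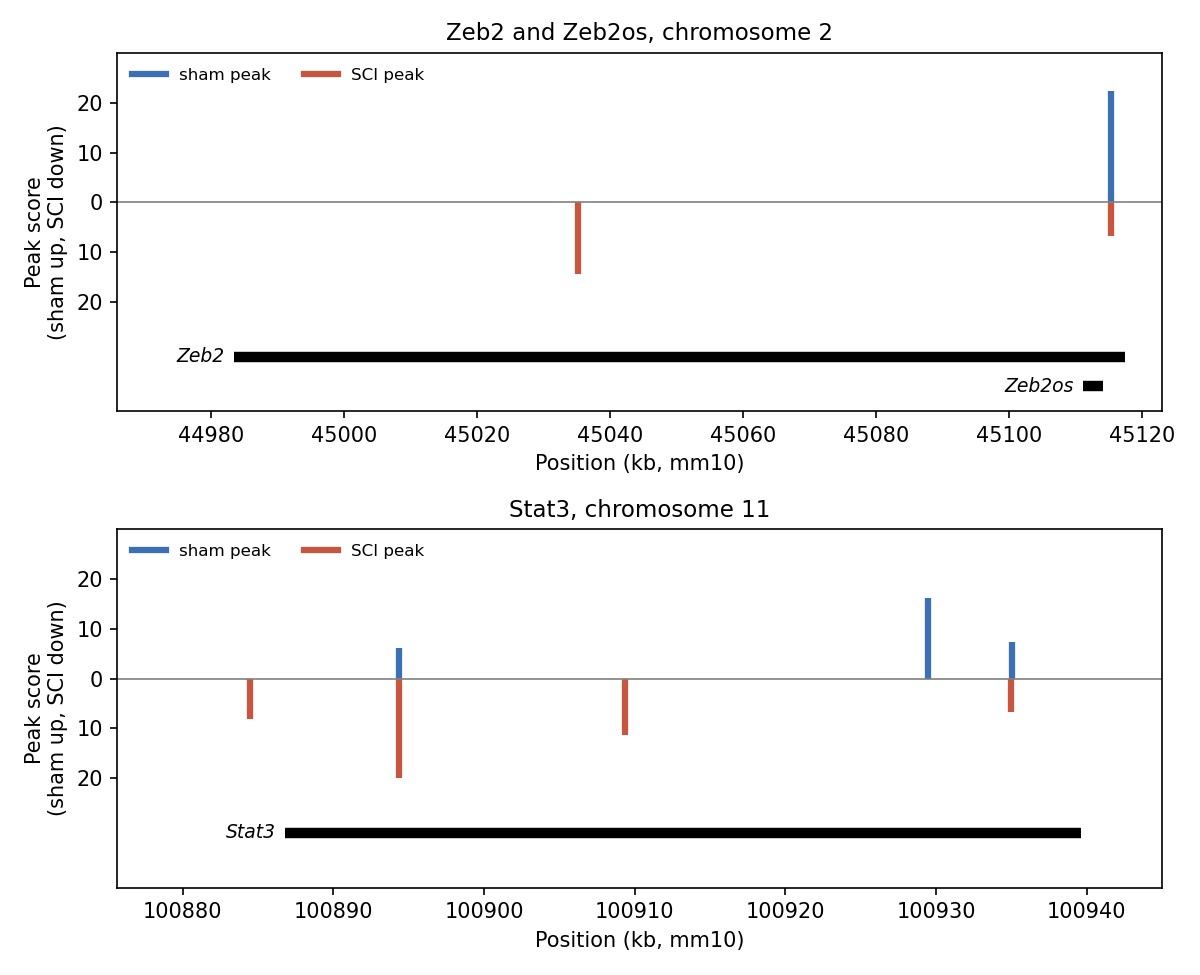
Peaks at Zeb2 and Zeb2os (upper panel) and at Stat3 (lower panel). Each bar is 1 peak at its centre (x axis, position in kb, mm10) with its score in its own list (y axis, sham upwards, SCI downwards), and black bars are genes; the peak beside Zeb2os scored 22.4 in sham and 6.74 in SCI, and the highest SCI peak at Stat3 scored 19.96.

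The 10 highest peaks at genes lay at different genes in the 2 lists, though most of these genes had lower-ranked peaks in the other list. In sham they included Vmn2r-ps16, Pisd-ps2, Sfi1 with Gm33862, Gm40034, Cd36, Garnl3, Zfp978, Smpd4 and Gm23057. Scores ran from 167 at the pseudogene Vmn2r-ps16 (chromosome 4, 146485640 to 146485821) to 87.2 beside Gm23057 (chromosome 9, 72637374 to 72637486). The peak inside Cd36, a fatty acid and lipoprotein receptor, lay at 17805512 to 17805639 on chromosome 5 with a score of 125. Cd36, Gm40034 and Gm23057 had no SCI peak, while Zfp978 had 6, Garnl3 had 3 and Smpd4 had 1. Of these 10 sham peaks, 3 were shared with SCI, those at Vmn2r-ps16, Pisd-ps2 and Sfi1.

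In SCI the genes were Dennd1b with 4930596I21Rik and Gm18553, Gm12751, Adamts6, Eda2r with Gm18111, Alg9, Polr2b, Gm36787, Gm40685, Gm3252 and Cnot8. The score was 108 inside Dennd1b (chromosome 1, 138979962 to 138980114) and 54.3 inside Cnot8, a subunit of the deadenylase complex (chromosome 11, 58105859 to 58105928). Adamts6, a secreted metalloproteinase gene, held a peak at 104493019 to 104493141 on chromosome 13 with a score of 71.1, and Polr2b, a subunit of RNA polymerase II, a peak at 77332977 to 77333076 on chromosome 5 with a score of 57.8. Of these 10 SCI peaks, 2 were shared with sham, at Adamts6 and beside Gm36787. Sham peaks at other positions were present at Dennd1b (6), Alg9 (5), Cnot8 (4), Eda2r (2) and Polr2b (1). The 5 highest SCI peaks had no gene within 5 kb, and the first, on chromosome 12 at 3109848 to 3110062, scored 1597.

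Most positions belonged to 1 list, yet far more were shared than shuffled peaks gave. The 10 strongest shared positions lay at Frk, Sfi1 with Gm33862, Il2, Crtc1, Abcf2, Pisd-ps2, Gm36063, Mcm5 and the T cell receptor genes Tcra and Tcrd with Gm30275, and 1 lay at no gene, on chromosome 19 at 14706855 to 14706907 in SCI. At Frk, a Src-family kinase gene, the SCI peak at 34561070 to 34561161 on chromosome 10 ranked 80 and the sham peak ranked 91. At Il2, the gene of interleukin 2, the SCI peak at 37122869 to 37122933 on chromosome 3 ranked 23 and the sham peak 173. The peaks beside Mcm5, a subunit of the replicative helicase, lay 4685 bp (SCI) and 4698 bp (sham) outside the gene and ranked 215 and 370.

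In total 7845 SCI peaks overlapped a sham peak, 21.6% (95% interval 21.2 to 22.1%). Shuffled SCI peaks gave a mean of 438 over 100 shuffles (range 393 to 497), so the observed overlap was 17.9-fold higher. From the other side, 7848 sham peaks were shared, 8.84% (8.66 to 9.03%), which was 17.7-fold over the shuffles. The shared share was highest among strong peaks, at 42.2% (40.5 to 43.8%) in the top 10% of SCI scores and 8.11% (7.24 to 9.05%) in the lowest 10%. For sham the values were 21.0% (20.1 to 21.8%) and 2.58% (2.26 to 2.93%). Across the shared peaks, which are not independent replicates, the scores in both lists had a Spearman rho of 0.113. The share also differed with the form of the score. Peaks whose score was 2 times the square root of a whole number, minus 1 (within 0.0001 of a whole number) were shared in 4.82% of 11999 cases in SCI, against 29.97% of the other 24250. A score of 5 has this form, and 2785 SCI peaks had it, so the contrast of deciles mixes strength with form. Among the other SCI peaks the share was 21.5% at scores from 5 to below 6 and 51.1% at 20 or more. With centres within 1000 bp counted as shared, the excess over shuffles was 3.99-fold.

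**Figure D2:**
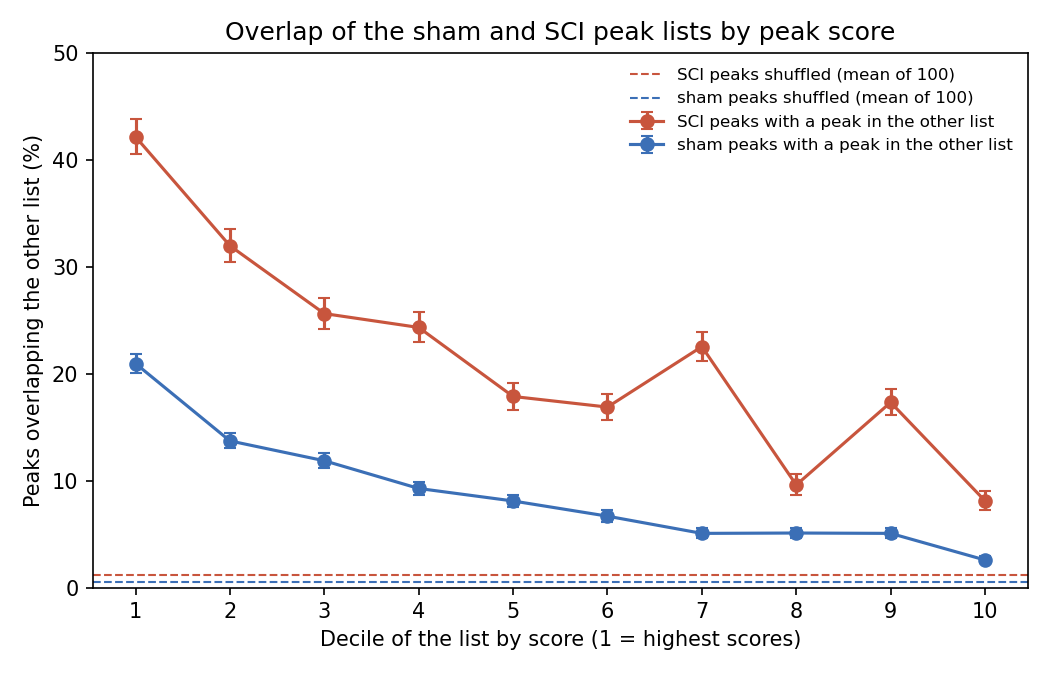
Percent of peaks that overlap a peak of the other list (y axis) by decile of the score (x axis, 1 is the highest), for SCI and sham peaks, with exact 95% binomial intervals as error bars; dashed lines are the means of 100 shuffles. The share goes from 42.2% to 8.11% in SCI and from 21.0% to 2.58% in sham. In SCI it does not fall at every step, with 9.6% in decile 8 and 17.3% in decile 9.

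Peaks lay slightly more often in and beside genes than shuffled peaks did, and by a similar margin in sham and SCI. Centres within 1 kb of a gene end made up 7.03% (6.86 to 7.20%) of the sham peaks and 7.21% (6.95 to 7.48%) of the SCI peaks, against 6.32% after shuffling in both. Among SCI peaks shared with sham the share was 8.07% (7.48 to 8.69%), and among the unshared ones 6.97% (6.68 to 7.28%). Protein-coding genes held 43.7% of the sham peaks and 43.4% of the SCI peaks, against 40.3 and 40.4% after shuffling. The shuffles drew positions evenly along each chromosome and left out no sequence where a peak could not be called. The small excess is therefore no measure of a preference of STAT3 for genes.

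Of 21887 protein-coding genes, 14591 had a sham peak and 9598 an SCI peak. Both conditions had a peak at 8173 genes, where independent draws matched on gene length gave 7624.5. A sham peak alone was found at 6418 genes and an SCI peak alone at 1425. The share with a peak went with gene length. In the longest 10% of genes 99.2% had a sham peak and 92.7% an SCI peak, and in the shortest 10% 24.1 and 10.96%. With the sham list shortened to its 36249 highest peaks, 9837 genes had one.

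Among the gene lists, the JAK-STAT3 pathway and its known targets, resting astrocyte genes and cell cycle genes had more members with a sham peak than nearly all random lists of the same lengths. The JAK-STAT3 list had a sham peak at 28 of 35 members (percentile 98.1 among 10000 random lists) and an SCI peak at 16 (percentile 71.0). Within 1 kb of gene ends 4 members had a sham peak (39.3) and 5 an SCI peak (96.6, short of the upper 2.5%). Jak1, the kinase below the interleukin-6 receptors, had 3 shared peaks, and so did Icam1, an adhesion molecule. Both were picked after their values were seen. Resting astrocyte genes had 18 of 20 members with a sham peak (98.0) and 11 with an SCI peak (67.7), and cell cycle genes 17 of 20 (98.9) and 7 (54.2). Vascular and fibroblast genes lay at the other end in sham, with 10 of 18 members (2.24) in sham and 10 (67.0) in SCI, but with a window of 10 kb they were at 3.46 in sham. They stayed in the lowest 2.5% in sham with scores at or above the list median (1.335), equal numbers of peaks (1.155) and matching on peak density (1.85). Over 13 lists, chance gives 0.325 in the upper 2.5% if members count as independent. With sham shortened to the SCI number of peaks, only the JAK-STAT3 list stayed there, with 22 members (99.6), against 14 resting astrocyte (96.7) and 10 cell cycle members (88.7). With random lists also matched on peak density within 1 Mb, only the cell cycle list stayed there (99.1), with the JAK-STAT3 list at 94.6 and resting astrocyte genes at 96.6. A window of 10 kb left the JAK-STAT3 list (99.1) and cell cycle genes (99.8) there in sham, but not resting astrocyte genes (84.9).

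Of the lists above, only cell cycle genes in sham exceeded the central 95% of the random counts in the main analysis (17 against an upper bound of 16). The JAK-STAT3, resting astrocyte and vascular counts in sham equalled a bound there, where the percentile depends on the treatment of ties. With sham shortened to the SCI number of peaks, the JAK-STAT3 count lay above its upper bound (22 against 20). The vascular count then lay below its lower bound (5 against 6). No other list lay in the lowest or highest 2.5% by percentile in either condition in the main analysis, with exceptions under other settings. With scores at or above the list median, microglia and macrophage genes reached percentile 97.6 in sham, and EMT and Zeb family genes fell to 1.53 in SCI. With a window of 50 kb, microglia and macrophage genes were at 99.3 and neutrophil and lymphocyte genes at 98.1 in SCI. Reactive astrocyte genes had a sham peak at 26 of 38 members (percentile 64.6) and an SCI peak at 13 (18.3). Microglia and macrophage genes had 18 of 25 in sham (83.6) and 12 in SCI (82.3). Neuron genes had 15 of 20 (29.9) and 11 (39.5), and oligodendrocyte lineage genes 16 of 20 (86.2) and 8 (41.4). Glial scar matrix genes had 19 of 20 (82.1) and 16 (84.0), EMT and Zeb family genes 15 of 18 (53.8) and 11 (40.7), and housekeeping genes 13 of 18 (90.3) and 9 (94.5). Neutrophil and lymphocyte genes had 6 of 14 (32.1) and 1 (5.3). Of the 4 protein-coding study genes, Zeb2 and Stat3 had peaks in both conditions (16.2 and 48.2).

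**Figure D3:**
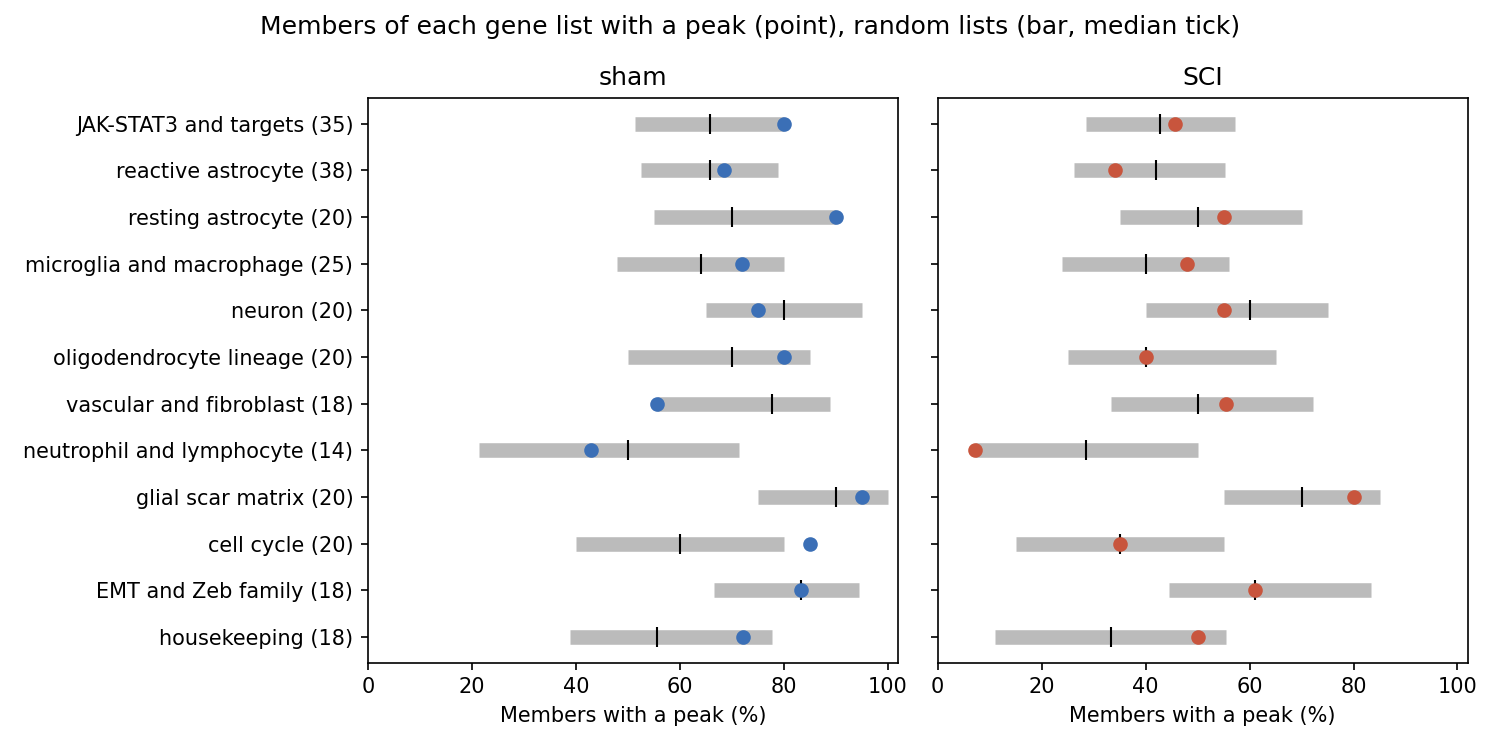
Percent of the members of each gene list with a peak (x axis, points; list size in brackets), in sham (left) and SCI (right). Grey bars span the central 95% of 10000 random lists matched on gene length and ticks mark their median; cell cycle genes in sham, 17 of 20, lie above the bar.

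Of 260 distinct genes on the lists, 17 had a peak in SCI and none in sham, and 90 the reverse. Among all 21887 protein-coding genes these numbers were 1425 and 6418. The share with an SCI peak alone was thus close to that of all these genes, and the share with a sham peak alone somewhat higher. The 17 are all named here. In the JAK-STAT3 list this was Mcl1, an anti-apoptotic gene, with a peak 2575 bp outside the gene (chromosome 3, 95665672 to 95665835, score 14.2, top 10.6%). Among reactive astrocyte genes these were Psmb8, the complement gene C3 and the growth-cone gene Gap43, whose best peaks scored 8.80, 7.90 and 6.89. The C3 peak lay inside the gene on chromosome 17 at 57214155 to 57214318. Among the other lists these were Atp1b2 (resting astrocyte), C1qb (microglia), Nefl and Slc17a6 (neuron), Col1a2, Kdr and Cldn5 (vascular and fibroblast), Elane (neutrophil), Chpf (glial scar matrix), Snai2 (EMT), and Ppia, Tbp and Actb (housekeeping). The peak beside Elane, a neutrophil protease gene, scored 12.6 (top 15.0%), that beside Nefl, a neurofilament gene, 11.9 (top 17.4%). Those at Cldn5 and Chpf scored 5, the lowest score in the list, and those at Kdr, Actb, Atp1b2, Tbp and Slc17a6 between 5.52 and 5.88.

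For the 90 genes with a peak in sham alone, the highest-ranked members, up to 2 per list, are named. In the JAK-STAT3 list they were the transcriptional repressor Bcl6 (chromosome 16, 23973241 to 23973430, inside the gene, score 30.5, top 2.58%) and Socs2. Of the astrocyte lists, Serping1 and Cd109 (reactive) and the glutamate transporter gene Slc1a2 and the glial transcription factor gene Sox9 (resting) had sham peaks alone, and Slc1a2 had 8 of them. Of the 7 such genes in the microglia and macrophage list, the highest-ranked were Spp1, encoding osteopontin, with a peak 145 bp outside the gene (chromosome 5, 104434871 to 104435060, score 44.8, top 0.58%), and Spi1, encoding the myeloid factor PU.1, with a score of 23.3. The highest-ranked in the other lists were Nefh and Slc6a5 (neuron), Cspg4 and Aspa (oligodendrocyte lineage), Col1a1 and Cdh5 (vascular and fibroblast), Csf3r and Ms4a1 (neutrophil and lymphocyte), Chsy1 and Lama1 (glial scar matrix), Ccnd2 and Cdc20 (cell cycle), Tgfb2 and Cdh2 (EMT), and Rpl13a and Rplp0 (housekeeping). With a window of 10 kb around genes, 9 of the 17 genes with an SCI peak alone also had a sham peak, and 17 of the 90 with a sham peak alone also had an SCI peak; with 50 kb these numbers were 17 and 75. With scores at or above the list median, 8 of the 17 and 60 of the 90 kept a peak in their own condition alone. Within 1 kb of gene ends, 1 of the 17 and 15 of the 90 did. With the sham list shortened to the SCI number of peaks, which leaves the SCI list as it is, 50 of the 90 did.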

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

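All tests in this part were chosen after the results were seen. The first signal lies on unplaced sequences, which only the alternative count of peaks on all sequences used. The unplaced sequence JH584304 carried 181 sham and 116 SCI peaks over a span of 114 kb in sham and 113 kb in SCI, and other unplaced sequences carried 93 and 46. It held 23 of the 25 highest scores of the whole sham list and 18 of the 25 highest of the SCI list, with maxima of 937 and 379. On JH584304, 80 of the 116 SCI peaks overlapped a sham peak, 69.0% (95% exact interval 59.7 to 77.2%). Shuffled within this sequence, which is dense with peaks, the SCI peaks gave a mean of 59.3 over 100 shuffles (range 47 to 70), so the observed overlap was 1.35-fold higher.

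The lower number of peaks after injury was set against depth. If the SCI list were the sham sites seen at lower depth, nearly all of its strongest peaks would be in the longer sham list. Of the top 1% of SCI peaks, 55.0% (49.7 to 60.2%) were in it. With 1 library per condition, it is unknown how far the strongest peaks of libraries of the same condition would overlap. The shortfall therefore cannot decide whether depth was the whole cause. An SCI ChIP library that was shallower relative to its control stays open. A step found in the scores, which may be the weight of 1 control read, was 2.58 times larger in sham than in SCI, and because the depths of the control libraries are not known here the depths of the ChIP libraries cannot be told apart from those of the controls. An effect of the injury itself stays open too, untested with 1 library per condition.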

How the results depend on the processing

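No paired analysis was possible because each condition has 1 STAT3 library. The motif alternatives were not run, since they need the genome sequence. The depth of the libraries is unknown, so a gene without a peak may have been missed. Of 59 alternative values for the main results, 25 stayed within the tolerance and 34 did not, where the tolerance was 1.5 times for counts and their ratio and the exact 95% interval for shares and folds. With scores at or above the median of both lists together, 46504 sham and 16003 SCI peaks were left, a ratio of 2.91. Whether the scores share a scale is not known, so this common cut is no check of the ratio. The percent of SCI peaks shared was 21.0 with scores at or above the list median, 13.9 with equal numbers of peaks, 14.7 with an overlap of at least 0.5 of each peak, 26.8 with centres within 1000 bp and 23.9 with peaks resized to 500 bp. The fold over shuffles was 34.4, 28.0, 26.0, 3.99 and 6.95 in the same order and 15.8 with centres within 200 bp. Chosen after seeing the data, leaving out scores of the square-root form gave 29.6% and 31.9-fold, and SCI peaks moved by 10 kb in place of shuffles gave 16.0-fold.

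The share of peaks at gene ends became 27.3% (sham) and 27.0% (SCI) within 5 kb, and 3.24 and 3.27% at ends of protein-coding genes. In sham it was 7.40% at or above the median score and 7.50% with equal numbers. Genes with a peak numbered 6328 in SCI and 4882 in both at or above the median score, 2866 (sham), 1248 (SCI) and 417 (both) within 1 kb of gene ends, and 18426 (SCI) and 18075 (both) within 50 kb. Lists in the upper 2.5% of random lists in sham went from 3 to 1 with equal numbers of peaks and 1 with matching on peak density. They went to 0 within 1 kb of gene ends and 0 within 50 kb, and in SCI from 0 to 2 within 50 kb. With scores at or above the list median there were 4 in sham. These were JAK-STAT3 (percentile 99.9), resting astrocyte (99.2), cell cycle (98.2) and microglia and macrophage genes (97.6). Within 10 kb there were 2 in sham. In sham the JAK-STAT3 list fell to percentile 39.3 within 1 kb of gene ends and 88.2 within 50 kb, resting astrocyte genes to 79.5 and 73.0, and cell cycle genes to 90.2 and 78.8, while vascular and fibroblast genes left the lower end at 42.9 and 72.4. Within 50 kb every member of these lists had a sham peak, so the percentiles there were the highest that could be reached. The fewer peaks or wider windows of these settings change such counts by construction, and the cause of the other changes was not tested. Of 130 list counts, 80 stayed within 1.5 times. Of 154 values for a peak at a named gene, 79 were lost within 1 kb of gene ends, 13 at or above the median score and 4 with equal numbers, and 12 and 42 were gained within 10 and 50 kb.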

Other observations

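The families and tests of this part were chosen after the data were seen. Protein-coding genes were grouped into 36 families whose symbols start with the same letters and which have at least 40 members, and members with a peak were set beside random genes of the same lengths. In sham, 5 families lay in the upper 2.5% of the random draws, where chance gives 0.9 if members count as independent. These were Rpl, encoding proteins of the large ribosomal subunit (35 of 53 members, random mean 21.4), Rps, with proteins of the small subunit and S6 kinases (30 of 44, 22.2), Mrpl of the mitochondrial ribosome (32 of 49, 25.3), Ube, enzymes of ubiquitin transfer (37 of 42, 31.9), and Slc, solute carriers (304 of 375, 288). With matching on peak density within 1 Mb as well, Mrpl (percentile 96.1) and Slc (94.5) left that range and Trim (54 of 68 members, 98.4) entered it. In SCI, Mrpl alone lay there with matching on length (20 of 49, 13.6; percentile 97.9), and no family did with matching on density as well, while Rpl was at 82.0 and Rps at 82.3. Shared peaks were at 12 of 49 Mrpl genes (random mean 4.28), 86 of 397 zinc-finger genes of the Zfp family (62.6) and 7 of 53 Rpl genes (3.00), all in the upper 2.5% under both kinds of matching. Eif genes, encoding translation initiation factors, were within the range in sham (81.6) and SCI (55.6). For the families the sham list was not shortened to the SCI number of peaks. Differences between sham and SCI by family, here and below, therefore cannot be told apart from the number of peaks.

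At the other end, 8 families lay in the lower 2.5% in sham with matching on length. These were the vomeronasal receptors Vmn (101 of 355 members, random mean 155), the olfactory receptors Olfr (268 of 1110, 307), the keratins Krt (11 of 53, 27.7), Pramel, expressed in germ cells (15 of 47, 25.3), the cytochromes P450 Cyp (59 of 99, 70.0), the secretoglobins Scgb (4 of 40, 13.6), Btbd (12 of 42, 21.3) and the gene models Gm (429 of 1329, 685). All 8 stayed in the lower 2.5% with matching on density. Random genes were drawn singly, while genes of a family can lie side by side and share a peak or lack one together. The random range may then be too narrow, and how well reads map to similar genes was not examined. In SCI the 5 families there were Vmn (49 of 355, 85.7), Pramel (3 of 47, 14.2), Gm (250 of 1329, 394), Btbd (7 of 42, 12.5) and Ccdc (55 of 137, 66.5), of which Btbd left the range with matching on density (4.76). Olfr (3.92) and Krt (15.0) were within the range in SCI, and so was the receptor family Gpr in sham (30.9). For shared peaks, Gm (69 of 1329, random mean 128), Vmn (7 of 355, 25.7) and Krt (0 of 53, 4.46) lay in the lower 2.5% under both kinds of matching. Cyp (8 of 99, 14.7) did so with matching on length only.

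The scores repeat the same values. Of the scores below 7, 36.7% in sham and 43.8% in SCI were 2 times the square root of a whole number, minus 1. A candidate explanation is that the score is made from the product of 2 read counts, with a fixed amount taken off per control read. Among 9801 step sizes from 0.01 to 0.5, a step of 0.1405 explained 31.7% of the remaining sham scores and a step of 0.0545 explained 40.0% of the remaining SCI scores, each within 5e-05 and with 1 or 2 control reads, while the 99th percentile of unrelated steps was 2.22 and 2.49%, so the best steps explained 14.3 and 16.0 times as much. This goes with a control read that weighed 0.1405 of a ChIP read in sham and 0.0545 in SCI, but the caller is not given in the sources used here and the reading stays a hypothesis.

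The shared positions were weighed against 2 technical explanations. Regional density of peaks is argued against: SCI peaks moved by 1 to 50 kb overlapped a sham peak at most 550 times in 12 moves, against 7845 unmoved. Places where the control library also gives reads may account for part of the sharing. Peaks with scores below 7 were grouped by the fewest control reads that explain the score with the step above. In SCI the share of peaks shared with sham was 3.46% (3.04 to 3.91%) for 0 reads, 10.3% (9.06 to 11.6%) for 1 and 11.9% (10.2 to 13.7%) for 2. It was 31.4% for scores that 0, 1 or 2 reads leave unexplained. The SCI intervals for 1 and 2 reads overlap. For sham peaks shared with SCI the values were 0.576, 2.47, 2.09 and 8.94%, with no rise from 1 to 2. Under the candidate form of the score, more control reads at a given score also take more ChIP reads. These values therefore cannot tell an effect of the control from one of the ChIP signal. STAT3 sites kept in both conditions would be shared too, and this biological explanation was not tested, since the motif search was not run.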
